A study of Mus musculus with 45 samples.

How the data were processed

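RNA was measured in sorted T cells of mice bearing B16 melanomas, a transplantable mouse skin tumour. Regulatory T cells (Tregs), the Foxp3-dependent CD4 T cells that restrain immune responses, came from tumours and from non-draining lymph nodes, and effector T cells came from tumours. Tregs were labelled WT (wild-type mice), N, HetNrp1def (Nrp1-deficient cells of heterozygous mice) or HetWT (Nrp1-sufficient cells of heterozygous mice). The genotype label of the N samples reads like that of HetNrp1def. The design text names homozygous deficient mice besides heterozygous ones, and the N samples were kept as a set of their own, from their titles. Per the labels' protocols, 5000 Tregs per library were sorted singly or doubly, amplified with a SMARTer ultra-low-input kit, made into libraries with Nextera XT and read on a NextSeq 500. The replicate labels were 2, 3 and 4 for single sorting and ds1 and ds2 for double sorting, the last 2 read as double from their names and numbers. Nothing in the labels says that replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical.

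The authors deposited read counts per gene symbol, made with STAR and featureCounts on mm10 per the submitters' processing notes. Tool versions, the gene annotation, the strand setting and the treatment of reads shared by several genes are not given in the sources used here. Genes that overlap, run antisense to another gene or share sequence with a paralog (Gzma and Gzmb with other granzymes, Ccl3 with Ccl4, Bcl2a1b with Bcl2a1d, the Gbp family) are therefore uncertain. The authors also deposited log2 values, normalized and filtered, for 10832 of the 23420 genes, with limma named in the submitters' processing notes. In that log2 table each gene had an equal mean in all 5 replicate numbers (the means of the numbers lay at most 3.8e-13 apart, against a median of 1.45 in log2 CPM of the counts), and library means lay between 4.07 and 4.08. No other step behind the log2 values is given in the sources used here.

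Total counts per library ran from 2945638 to 35787148 (median 10248080) and genes with a count from 10896 to 21237 (median 14434). The 9 ds2 libraries were the shallowest (2945638 to 5408375), and Malat1, a nuclear RNA, took a median 1.70% of their counts against 0.513% over all 45 libraries. The 9 ds1 libraries had TMM factors from 0.550 to 1.11. The first principal component of log2 CPM (counts scaled to a common library size) held 17.9% of the variance, of which replicate number explained 85.0% and group 6.40%. The second held 11.4%, of which group explained 89.0%. Y-linked reads were found in 7 libraries. Symbols matched GENCODE vM21, the mm10 annotation used here for coordinates, for 92.98% of genes (21777). 556 genes had no count in any library.

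Libraries of a group were compared by chi-square per degree of freedom (df) of their counts. In 4 pairs it was 2.42 to 2.75 (r 0.998 to 0.999), while the other 86 pairs of a group lay at 68.4 or above (median 180.3) with r of at most 0.970. The lowest between groups, 14.9, lay below all those 86, and why was not tested. The limit of 5 was set after seeing these values. The pairs were replicates 3 and 4 of the HetWT and of the HetNrp1def lymph node groups, and ds1 and 4 of the HetWT and of the HetNrp1def tumour groups. Each pair was summed and counted as 1 sample, which left 41 samples, with 4 in each heterozygous group and 5 in the others. The design fixed beforehand named all 45 libraries in the fit, so this joining departs from it and was decided after seeing the data, and the 45 libraries as deposited are kept as an alternative. The 2 tumour pairs each join a library named as double sorted with one that is not. The joined samples kept the number 4 and counted as single-sorted in the figures and wherever samples were split by sorting.

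Genes were tested with edgeR 4.0.16 in R 4.3.3: TMM normalization, filterByExpr by group (14668 genes kept), robust quasi-likelihood fits of all 41 samples with 32 residual df, no covariates, and Benjamini-Hochberg adjusted p below 0.05 within each contrast. The 14 contrasts and their tests were fixed before the data were examined. The tissue contrasts of N, HetNrp1def and HetWT Tregs, 3 in number, were added after seeing the data. Expression is given as CPM with TMM, as mean ± SD. The replicate number was not in the model. Same-numbered samples were taken to pair where the r of their deviations from the group means was over 0.1 in every pair, which held in HetNrp1def and HetWT against WT (lowest r 0.117 in each) and HetNrp1def against HetWT (0.143) in the lymph node, 4 pairs each. That pairing comes from the values and not from the labels. Nrp1, Foxp3 and Ifng were also tested singly with two-sided exact permutation tests on log2 CPM, 33 tests in 1 family. Where a group held no count of a gene, its fold is a floor set at 3 counts over the group. With 1 to 3 counts, the ratio of summed counts has a 95% exact interval. Amplified reads without molecular identifiers are not independent molecules, so these intervals and floors cover counting error only.

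Gene lists, 31 in number, were fixed before the data were examined. They covered Treg identity, Treg suppressive effectors, activated tumour Tregs, the IFNg and Th1 programme, IFNg response, type I interferon response, checkpoint receptors, naive and lymphoid homing genes, chemokines and their receptors, Th2, Th17 and Tfh programmes, proliferation, apoptosis and survival, glycolysis and hypoxia, oxidative phosphorylation, sterol and fatty acid synthesis, AKT, mTOR and FOXO signalling, semaphorin and neuropilin partners, immediate early and stress genes, sex-linked genes and mitochondrial RNA. The other 11 hold markers of melanoma, macrophages and monocytes, neutrophils, dendritic cells, B cells, CD8 T cells, NK cells, conventional CD4 T cells, erythroid cells, fibroblasts and endothelium. The mitochondrial list has 0 genes in the count table, and the neutrophil and erythroid lists have 2 tested genes each, under the minimum of 3, so 28 lists were tested per contrast. Lists overlap: Ctla4 and Entpd1 stand in the identity, suppressive and checkpoint lists, the conventional CD4 list shares Igfbp4, Tcf7, Lef1, Dapl1, Bach2, Il7r and Satb1 with the naive list, the CD8 list shares Gzmb and Prf1 with the suppressive list and Ccl5 with the chemokines, and Ccr2 stands among both chemokines and macrophage markers. Camera (limma 3.58.1) on log2 CPM with a prior count of 2 compared each list with the other genes, with a preset correlation of 0.01, adjusted over the 28 lists of a contrast. The calls were repeated with an estimated correlation, and with fry, which tests whether a list's genes move, on balance, one way.

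The text names Nrp1, Foxp3 and Ifng in every comparison, the 6 highest and 6 lowest called genes with a mean of at least 10 CPM and one direction in at least 4 of 5 same-numbered pairs (unnamed, immunoglobulin and T cell receptor genes left out), and up to 4 called and 2 uncalled members of each list, by adjusted p and by CPM. Other genes were chosen after their values were seen, and the text says so. The results of some genes under this rule are not reported here.

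On simulated counts with 50 genes changed at each of 4 fold sizes, edgeR recovered 2% of 2-fold, 20% of 4-fold, 60% of 8-fold and 74% of 16-fold changes for WT tumour against lymph node Tregs (14165 genes), with 3 false calls of 81. For N against WT tumour Tregs (14124 genes) it recovered 2%, 18%, 62% and 86%, with 2 false calls of 86. For HetNrp1def against WT tumour Tregs (14178 genes) it recovered 0%, 14%, 52% and 78%, for HetNrp1def against HetWT (14230 genes) 0%, 14%, 42% and 58%, and for WT Tregs against effector T cells (14180 genes) 0%, 18%, 42% and 76%. DESeq2 1.42.0 made 29 false calls of 148 and 42 of 143 on the first and second simulation (14668 genes), so its longer lists are given only as an alternative.

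Alternatives fixed before the data were examined were DESeq2, DESeq2 size factors in edgeR, no filter on low counts, the replicate number as a block, sorting as a covariate, single-sorted or double-sorted libraries alone, only the groups of a contrast, a minimum fold, leaving out each library in turn, limma on the authors' log2 values, fry and an estimated correlation. Chosen after seeing the data were the 45 libraries as deposited, leaving out the ds1 libraries, Y-linked reads or the melanoma mean as covariates, limma voom with library weights, limma on log2 CPM of the genes in the authors' log2 table, that table with a block or without 1 or 2 WT tumour samples, and leaving out each sample of a comparison in turn for gene lists.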

Results

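Gene expression was measured in 45 libraries of sorted mouse T cells in 9 groups of 5. Regulatory T cells (Tregs) labelled WT, HetWT, HetNrp1def or N came from B16 melanomas and from non-draining lymph nodes, and effector T cells came from tumours. The design asks how Tregs differ between tumour and lymph node, and whether loss of neuropilin-1 (Nrp1) changes them in homozygous mice or in heterozygous mice, which carry Nrp1-deficient and Nrp1-sufficient Tregs side by side. Total counts per library ran from 2945638 to 35787148, with a median of 10248080. In each heterozygous Treg group, 2 libraries differed by little more than counting noise (chi-square per df 2.42 to 2.75) and were counted as 1 sample. That left 41 samples, 4 in each of the 4 heterozygous groups and 5 in each other group. Unless another test is named, adjusted p for genes come from edgeR and those for gene lists from camera (limma).

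Nrp1, the targeted gene, encodes a membrane co-receptor for semaphorins and growth factors and marks many thymus-derived Tregs. It lies on chromosome 8 (mm10, 128358604 to 128503363, plus strand). In tumour Tregs it stood at 171 ± 78.9 CPM (SD, n = 5) in WT, 154 ± 21.6 CPM (n = 5) in N, 154 ± 71.2 CPM (n = 4) in HetNrp1def and 155 ± 59.3 CPM (n = 4) in HetWT. Samples ran from 103 to 290.3 CPM in WT, 130.1 to 184 in N, 105 to 259.5 in HetNrp1def and 95.1 to 231 in HetWT tumour Tregs. In lymph node Tregs it stood at 359.7 ± 64.2 CPM in WT (265 to 412), 211 ± 75.5 CPM in N (144 to 338), 197 ± 96.4 CPM in HetNrp1def (146 to 342) and 583 ± 573 CPM in HetWT (219 to 1439). Effector T cells held 13.1 ± 6.59 CPM (2.70 to 19.2). Nrp1 counts in the groups labelled deficient were therefore within the range of WT in tumours. The deleted exons are not given in the sources used here, and counts over the whole gene do not check the knockout, so the genotype groups below are those the labels name. In exact two-sided permutation tests of log2 CPM, the Nrp1 difference was -1.17 between WT tumour and lymph node Tregs (p = 0.0159, adjusted p = 0.0873 over 33 tests) and 3.84 between WT tumour Tregs and effector T cells (exact p = 0.00794, adjusted p = 0.0655). Between N and WT lymph node Tregs it was -0.81 (exact p = 0.0238, adjusted p = 0.112) and between HetNrp1def and WT -0.95 (exact p = 0.0397, adjusted p = 0.164). None of the 33 exact tests of Nrp1, Foxp3 and Ifng passed an adjusted p of 0.05, and the lowest adjusted p was 0.0655.

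Foxp3 (chromosome X, 7573644 to 7595245, plus strand), the transcription factor that defines Tregs, was low in all Treg groups. It stood at 20.04 ± 13.9 CPM in WT, 18.1 ± 5.93 CPM in N, 27.7 ± 22.1 CPM in HetNrp1def and 28.0 ± 21.9 CPM in HetWT tumour Tregs, against 0.383 ± 0.695 CPM in effector T cells. In lymph nodes it stood at 12.9 ± 25.0, 17.7 ± 28.8, 17.6 ± 30.4 and 14.1 ± 14.6 CPM in the same order of genotypes. The ds2 library was the highest for Foxp3 in 8 of 8 Treg groups, with 32.0 to 68.8 CPM in the 4 lymph node ds2 samples against 0 to 20.1 CPM in the other 14. Ifng (chromosome 10, 118441046 to 118445892, plus strand), the cytokine interferon gamma, stood at 107 ± 55.8 CPM in WT, 287 ± 215 CPM in N, 199 ± 156 CPM in HetNrp1def and 167 ± 219 CPM in HetWT tumour Tregs. Lymph node Tregs held 3.84 ± 2.97, 17.4 ± 10.4, 7.32 ± 9.29 and 68.8 ± 103 CPM, and effector T cells 5.44 ± 4.98 CPM. The exact test gave p = 0.00794 for WT tumour against lymph node Tregs, the smallest possible, and an adjusted p of 0.0655. It gave the same values for Foxp3 and Ifng in WT tumour Tregs against effector T cells (differences 5.74 and 5.67), and for Ifng in N against WT lymph node Tregs a difference of 2.75 (exact p = 0.0159, adjusted p = 0.0873).

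**Figure D1:**
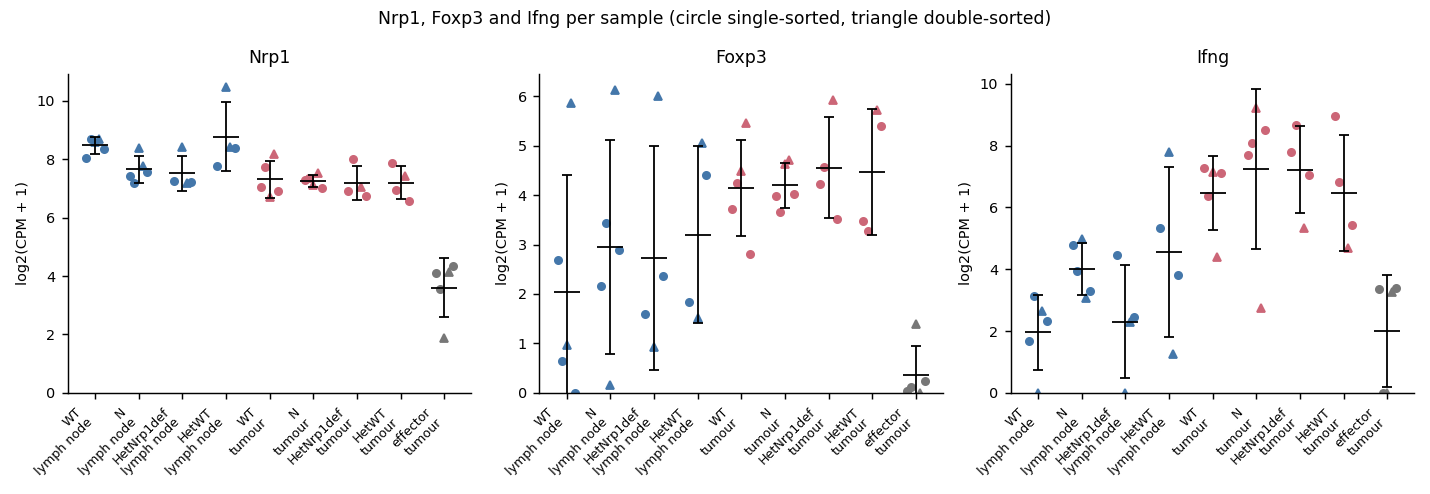
Expression of Nrp1, Foxp3 and Ifng as log2(CPM + 1) per sample, by group. Circles are single-sorted and triangles double-sorted samples, and bars give the mean ± SD. Nrp1 in tumour Tregs overlaps between the 4 genotypes, and effector T cells sit at 2.70 to 19.2 CPM.

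WT Tregs of tumour and lymph node were compared for the tissue change in unmodified cells. Tumour Tregs were lower in the list of naive and lymphoid homing genes and higher in the suppressive effector, activated Treg and glycolysis lists. Ccr7, the receptor that guides T cells into lymph nodes, fell from 224 ± 52.1 to 28.0 ± 12.8 CPM (log2 fold change -3.00, SE 0.44, adjusted p = 1.3e-05). Gzmb, the protease granzyme B, rose from 14.2 ± 10.6 to 1199.8 ± 542 CPM (log2 fold change 6.40, SE 1.22, adjusted p = 0.00336). Hif1a, the transcription factor of the response to low oxygen, rose from 242 ± 45.4 to 1398 ± 269.9 CPM (log2 fold change 2.53, SE 0.32, adjusted p = 5.6e-07). Nrp1 had a log2 fold change of -1.07, adjusted p = 0.314, and Foxp3 one of 0.64, adjusted p = 0.919. Nrp1 was called under 4 of 19 alternatives, among them limma on the authors' log2 values (-2.03, adjusted p = 0.00403), with adjusted p from 0.00403 to 1 over the 19. Foxp3 was below 0 in 3 of the 19. The Foxp3 value rests on WT lymph node ds2 (57.4 CPM, against a group median of 0.951), being 3.52 without it, and the difference in mean log2 CPM was 3.03 (exact p = 0.0952). Of 14668 genes tested with edgeR, 75 were higher and 53 lower in the tumour. Without WT tumour replicate 2, WT lymph node replicate 2 or WT lymph node ds1 the count of 128 was 78, 84 and 82. It was 382 with the replicate number as a block, 2 in the double-sorted libraries alone and 486 with DESeq2.

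The list of naive and lymphoid homing genes fell in the tumour. Of its 18 tested members 12 were lower (15 adjusted over the list alone), with a mean log2 difference of -2.77 (camera adjusted p = 2.8e-29, and 3.6e-08 with an estimated correlation). Tcf7, a transcription factor of naive and memory T cells, fell from 259 ± 38.3 to 45.4 ± 28.2 CPM (log2 fold change -2.51, adjusted p = 0.000778). S1pr1, which lets T cells leave lymphoid organs, had a log2 fold change of -2.37, Satb1 one of -1.92 and Igfbp4 one of -4.88 (adjusted p = 0.000556, 0.00184 and 0.000930). Lef1, a partner of Tcf7 in naive T cells, stood at -1.70 (adjusted p = 0.0927). The conventional CD4 list, which shares 7 genes with the naive list (Igfbp4, Tcf7, Lef1, Dapl1, Bach2, Il7r and Satb1), had 5 of 10 members lower (6 adjusted over the list alone, adjusted p = 0.000577 with an estimated correlation). Among the lowest called genes were Faim3, an apoptosis inhibitor of lymphocytes (-8.63, adjusted p = 0.0112), Dapl1 (-5.16, adjusted p = 0.0150) and the orphan receptor Gpr83 (-4.96, adjusted p = 0.00389).

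The suppressive effector list rose, with 2 of 16 members called (8 adjusted over the list alone), a mean of 2.40 and an adjusted p of 1.8e-05 with an estimated correlation. Its called members were Gzmb and Lag3, an inhibitory receptor that binds MHC class II (4.42, adjusted p = 0.0472). Ctla4, the inhibitory receptor for CD80 and CD86, stood at 2733 ± 1986 against 486 ± 246 CPM (adjusted p = 0.0755), and Fgl2 at a log2 fold change of 3.23 (adjusted p = 0.107). The list of activated tumour Tregs rose as well, by a mean of 1.81, with 2 of 20 members called (11 adjusted over the list alone, adjusted p = 0.000104 with an estimated correlation). Tnfrsf9, the co-stimulatory receptor 4-1BB, rose from 144 ± 80.8 to 1184 ± 360.0 CPM (adjusted p = 1.3e-05). The checkpoint list had 2 of 12 members higher (6 higher and 2 lower adjusted over the list alone), led by Havcr2, the receptor TIM-3 (7.04, adjusted p = 0.000169), and its adjusted p of 0.0229 became 0.0627 with an estimated correlation. With the preset correlation that call was lost without WT lymph node ds2, WT tumour replicate 2 or WT tumour ds2. With the authors' log2 values the suppressive, activated and checkpoint lists turned down against the other genes and were not called (means 0.14, 0.0672 and -0.48). There activated genes, taken from the mean of the replicate number, had the opposite sign to the counts in 12 of 45 libraries, among them WT tumour ds1 and ds2 (-0.60 and -2.33 against 1.23 and 1.06). Without ds2 the 3 means were 0.68, 0.62 and -0.14, and without both 1.15, 0.97 and 0.20. Pdcd1, the receptor PD-1, stood at 2.00 (adjusted p = 0.0741). Of the Treg identity list 1 of 19 members was higher and 1 lower (5 and 1 adjusted over the list alone, adjusted p = 0.335). They were Tnfrsf18, the receptor GITR (1.75, adjusted p = 9.9e-05), and Gpr83.

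Interferon genes were also higher in the tumour. The IFNg and Th1 list had 3 of 18 members called (8 adjusted over the list alone, adjusted p = 0.000104 with an estimated correlation). Ifngr1, the ligand-binding chain of the interferon gamma receptor, rose from 154 ± 34.3 to 1171 ± 697 CPM (log2 fold change 2.93, adjusted p = 5.5e-06). Il12rb2, the signalling chain of the IL-12 receptor, had a ratio of summed counts of 322 (95% exact interval 88.9 to 2663). Ifng itself had a log2 fold change of 4.78 (adjusted p = 0.0994), and 7 of 19 alternatives called it, with adjusted p from 0.00110 to 1. In the IFNg response list 1 of 31 members was called, the GTPase Iigp1 (1.99, adjusted p = 0.000873), and 2 adjusted over the list alone (adjusted p = 0.00441 with an estimated correlation). In the type I interferon list 4 of 23 rose (9 adjusted over the list alone, adjusted p = 0.0110 with an estimated correlation). Those were Zbp1, a sensor of viral nucleic acids (2.28), Ifit3 (2.04), Ifi27l2a (1.19) and the exonuclease Isg20 (2.60).

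The glycolysis and hypoxia list rose in the tumour. Of its 26 tested members 7 were higher (18 adjusted over the list alone), with a mean log2 difference of 2.00 (camera adjusted p = 4.5e-18, and 4.9e-08 with an estimated correlation). The glycolytic enzymes aldolase (Aldoa), Gapdh and Tpi1 had log2 fold changes of 2.25, 1.60 and 2.72 (adjusted p = 5.6e-07, 0.000873 and 0.00143). The oxidative phosphorylation list had 0 of 31 members called, also adjusted over the list alone (mean 0.00, adjusted p = 0.544). In the sterol and fatty acid list 1 of 23 members rose, and 3 adjusted over the list alone (adjusted p = 0.0376 with an estimated correlation). The immediate early list had 1 of 22 members higher, the AP-1 subunit Fosl2 (4.27, adjusted p = 0.0375), and 3 adjusted over the list alone (adjusted p = 0.0376 with an estimated correlation). Leaving out 1 sample at a time, the sterol and immediate early calls with an estimated correlation were lost in 6 of 10 cases each.

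Chemokine genes moved both ways, with 4 of 19 members higher and 1 lower (10 and 3 adjusted over the list alone, adjusted p = 0.00220 with an estimated correlation). Ccl3, an inflammatory chemokine, rose from 0.0573 ± 0.128 to 189 ± 140.0 CPM (adjusted p = 0.00198) and Ccl5, which attracts T cells, from 129.9 ± 106 to 1129 ± 507 CPM (adjusted p = 0.0213), while Ccr6 fell (log2 fold change -4.30). Ccr2 and Cxcr6 stood at 3.02 and 3.14 (adjusted p = 0.0548 and 0.0728). The apoptosis and survival list had 1 of 21 members higher and 1 lower, also adjusted over the list alone (adjusted p = 0.935). They were the pro-apoptotic Pmaip1 (3.51, adjusted p = 0.0153) and the anti-apoptotic Bcl2, which fell from 352 ± 110.3 to 40.9 ± 23.8 CPM (adjusted p = 0.000136). The proliferation list had 0 of 30 members called, also adjusted over the list alone, and its adjusted p of 0.00754 became 0.176 with an estimated correlation. The Th2, Th17 and Tfh list had 1 of 14 members lower, Ccr6 (adjusted p = 0.603), and 1 higher and 1 lower adjusted over the list alone. The AKT, mTOR and FOXO list (mean -0.22, adjusted p = 0.0574), the semaphorin list (0.05, adjusted p = 0.603) and the sex-linked list (0.47, adjusted p = 0.913) had no member called over all genes, and 1, 1 and 0 lower adjusted over the list alone. The apoptosis, Th2, oxidative phosphorylation, semaphorin and endothelial lists had means at 0 or above, while their direction in the test, which compares a list with the other genes, was down (median of all genes 0.14).

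Markers of other cell types differed between the same samples. Melanoma genes were higher in the tumour (mean 4.78, 1 of 12 members called, 11 adjusted over the list alone, adjusted p = 0.0376 with an estimated correlation). Mlana, a melanosome protein, was at least 1072-fold higher, with no count in lymph node samples and 70.3 ± 71.7 CPM in tumour samples, and Cited1, a regulator expressed in melanocytes, at least 314-fold higher. The pigment enzymes Dct and Tyrp1 stood at 500.2 ± 670.3 and 405 ± 415 CPM in the tumour (adjusted p = 0.0713 and 0.0713). Eps8 had a ratio of 1864 (95% exact interval 638 to 9039), the secreted glycoprotein gene Spp1 one of 822 (95% exact interval 281 to 3987), and Car6, a carbonic anhydrase, a log2 fold change of 10.51 (adjusted p = 0.0319). B cell genes were lower in the tumour, 2 of 9 members (6 adjusted over the list alone, adjusted p = 0.0376 with an estimated correlation), among them Ms4a1, the antigen CD20 (-8.58), but in double-sorted libraries alone the list stood at 0.59 and Ms4a1 at 0.10. The CD8 list had 3 of 8 members higher, Nkg7, Gzmb and Ccl5 (4 adjusted over the list alone, adjusted p = 0.00255 with an estimated correlation), of which Gzmb and Ccl5 also stand in the suppressive and chemokine lists, and Cd8b1 stood at -0.53 (adjusted p = 0.905). Macrophage and fibroblast calls (adjusted p = 0.00672 and 0.0297) became 0.330 and 0.350 with an estimated correlation, with 0 of 18 and 0 of 9 members called (2 and 1 adjusted over the list alone). The macrophage mean of 1.19 was 0.68 without WT lymph node ds2, where its call was lost, and 1.85 without WT tumour ds2, and the fibroblast call was lost in 5 of 10 leave-outs. The melanoma and B cell calls with an estimated correlation were lost in 7 of 10 leave-outs each. The dendritic cell (adjusted p = 0.603; median −0.04, mean 0.43), NK cell (0.428) and endothelial (0.544) lists were not called, and Xcr1, a receptor of cross-presenting dendritic cells, was the single called member among them (6.47, adjusted p = 0.0347), with 2 dendritic cell genes higher and 1 endothelial gene lower adjusted over the list alone.

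**Figure D2:**
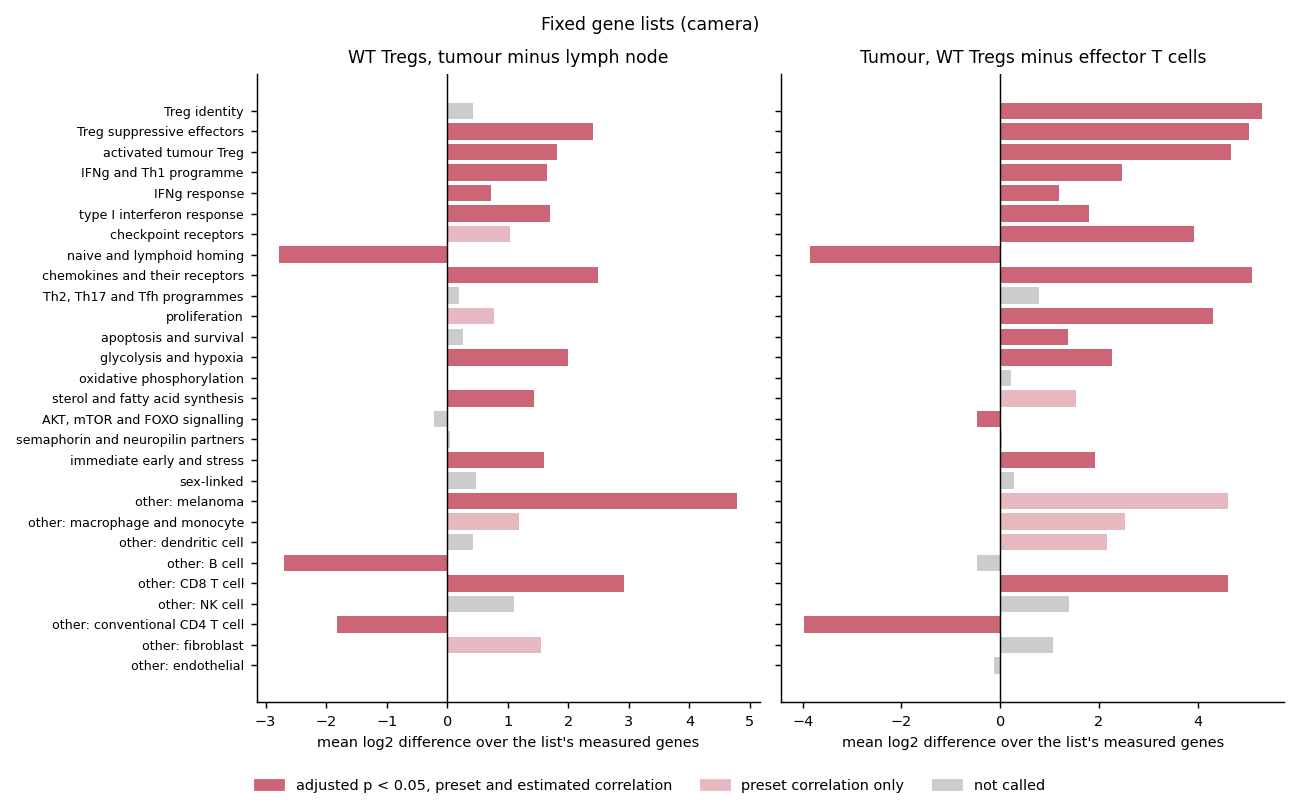
Mean log2 difference of the 28 tested gene lists, for WT tumour against WT lymph node Tregs and for WT tumour Tregs against effector T cells. Dark bars were called by camera with the preset and the estimated correlation, light bars with the preset one alone, and grey bars with neither. The naive list lies at -2.77 and -3.85, and the glycolysis list at 2.00 and 2.27.

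WT Tregs were set against tumour effector T cells, higher in naive genes than lymph node Tregs, so Treg identity and activation are not separated. Ikzf2, the transcription factor Helios, stood at 1049 ± 197 against 12.7 ± 10.1 CPM (log2 fold change 6.35, SE 0.45, adjusted p = 1.3e-15), and Il2ra, the high-affinity IL-2 receptor chain CD25, had a log2 fold change of 6.03 (adjusted p = 2.5e-14). Ctla4 stood at 2733 ± 1986 against 14.1 ± 11.1 CPM (log2 fold change 7.61, SE 0.87, adjusted p = 1.2e-07), Foxp3 had a log2 fold change of 5.67, adjusted p = 0.00968, and Nrp1 one of 3.71, adjusted p = 9.8e-08. Ifng stood at 4.30, adjusted p = 0.0535, and was called under 11 of 19 alternatives. Foxp3 lost its call under 4 of 19 alternatives, among them the authors' log2 values (1.16) and double-sorted libraries alone (5.39). Of 14668 genes tested with edgeR, 602 were higher and 236 lower in Tregs. The count of 838 was 51 in the double-sorted libraries alone, 1284 with the replicate number as a block and 1574 with DESeq2.

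Of the Treg identity list 16 of 19 members were higher in Tregs (mean 5.29, adjusted p = 1.1e-10 with an estimated correlation). So were 11 of 16 suppressive effectors (mean 5.04, adjusted p = 1.1e-09 with an estimated correlation), among them Ebi3, a subunit of IL-35 (6.75), and Entpd1, the ectonucleotidase CD39 (6.64). Gzmb stood at 1199.8 ± 542 against 0.294 ± 0.361 CPM (adjusted p = 1.9e-06). Of the activated Treg list 16 of 20 rose above effector T cells (mean 4.68, adjusted p = 4.6e-10 with an estimated correlation), with Tnfrsf9 at 5.60, the inhibitory lectin receptor Klrg1 at 9.74 and the co-stimulator Icos at 3.13. Checkpoint receptors had 6 of 12 members higher (adjusted p = 5.9e-06 with an estimated correlation), including Pdcd1 (4.96) and Havcr2 (7.37). Chemokines and their receptors had 11 of 19 higher (adjusted p = 1.9e-06 with an estimated correlation), with a ratio of 15144 (95% exact interval 4192 to 125053) for Ccl4 and 5163 (95% exact interval 1766 to 25037) for Ccl3, and Ccr2 at 7.52. Adjusted over the list alone, 18 identity genes were higher and 1 lower, 13 suppressive, 18 activated, 8 checkpoint and 13 chemokine genes were higher, and 1 checkpoint gene was lower. Also among the highest were the immunoglobulin-family receptor Gp49a, with a ratio of 5176 (95% exact interval 929 to 204485), and Il1r2, the decoy receptor for IL-1 (10.63, adjusted p = 9.0e-09).

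Effector T cells held more of the naive programme than tumour Tregs. Of the naive list 16 of 18 members were lower in Tregs (16 adjusted over the list alone), with a mean of -3.85 (adjusted p = 6.7e-09 with an estimated correlation). Ccr7 stood at 28.0 ± 12.8 CPM in Tregs against 617 ± 60.9 CPM in effector T cells, and Tcf7 at 45.4 ± 28.2 against 961 ± 327 CPM (adjusted p = 5.4e-10 and 4.0e-09). Dapl1 (-7.63), Lypd6b (-8.49), Ggt5 (-8.11), Pdlim4 (-7.72) and Cnga1 (-7.71) were among the lowest called genes, and Adh1, an alcohol dehydrogenase, had a ratio of 729 (95% exact interval 249 to 3539.5) in favour of effector T cells. The conventional CD4 list had 7 of 10 members lower in Tregs (8 adjusted over the list alone, adjusted p = 1.5e-06 with an estimated correlation). The AKT, mTOR and FOXO list had 1 of 20 members higher and 3 lower (adjusted p = 0.00940 with an estimated correlation), Phlpp1, a phosphatase of AKT (3.85), against Foxo1 (-1.49), Pik3ip1 (-3.14) and Pik3cd (-1.35). The semaphorin list, which holds TGF-beta receptors, had 2 of 16 lower, Tgfbr2 (-1.88) and Tgfbr3 (-4.34), and was not called (adjusted p = 0.450). Adjusted over the list alone, 1 AKT, mTOR and FOXO gene was higher and 5 lower, and 3 semaphorin genes were lower.

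Cell division genes were higher in Tregs, 20 of 30 members of the proliferation list (27 adjusted over the list alone, mean 4.32, adjusted p = 1.4e-07 with an estimated correlation). Mki67, a marker of dividing cells, stood at 267 ± 53.2 against 10.8 ± 10.5 CPM (adjusted p = 9.8e-11), and the mitotic kinase Cdk1 had a log2 fold change of 8.05. In the glycolysis list 12 of 26 were higher and 1 lower (adjusted p = 5.4e-07 with an estimated correlation), with Hif1a at 3.57 and Tpi1 at 4.50. The apoptosis list had 4 of 21 higher and 1 lower (adjusted p = 0.00866 with an estimated correlation), Pmaip1 (9.10) and the Bcl2a1 paralogs among the former and Bcl2 (-2.54) the latter. IFNg and Th1 genes (8 of 18), IFNg response genes (5 of 31), type I interferon genes (6 of 23) and immediate early genes (4 of 22) were higher too, with adjusted p of 3.5e-06, 0.000831, 0.0339 and 0.0443 with an estimated correlation. With the authors' log2 values Bcl2 stood at 0.57, and type I interferon and immediate early genes turned down against the other genes and were not called (means -0.0738 and -0.000286). Without WT tumour ds1 and ds2 these 3 values were 0.35, 0.65 and 0.43. Leaving out 1 sample at a time, the type I interferon and immediate early calls with an estimated correlation were lost in 2 and 6 of 10 cases. The sterol list had 3 of 23 higher, and its adjusted p of 0.000855 became 0.0983 with an estimated correlation. Adjusted over the list alone, the counts higher in Tregs were 16, 6, 9, 6, 10, 5 and 4 in that order. Oxidative phosphorylation (adjusted p = 0.612), Th2, Th17 and Tfh (0.429, with Gata3 called at 1.36) and sex-linked (0.918) lists were not called.

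Among markers of other cells, the CD8 list had 3 of 8 members higher in Tregs (adjusted p = 0.000530 with an estimated correlation), among them Nkg7 (5.13), while Cd8b1 stood at 0.90 (adjusted p = 0.707). Melanoma (5 of 12 called, adjusted p = 8.8e-07), macrophage (3 of 18, 5.4e-05) and dendritic cell (2 of 13, 0.00878) markers were higher in Tregs with the preset correlation, with adjusted p of 0.113, 0.113 and 0.245 with an estimated correlation. Tyrp1 stood at 405 ± 415 against 0.188 ± 0.327 CPM. In double-sorted libraries alone the melanoma mean was -0.0888. B cell (adjusted p = 0.429), NK cell (0.410), fibroblast (0.383) and endothelial (0.429) lists were not called, with Pecam1, an endothelial and leukocyte adhesion molecule, called at -2.69. Adjusted over the list alone, 4 CD8, 9 melanoma, 7 macrophage, 2 dendritic cell and 1 fibroblast genes were higher and 1 endothelial gene lower in Tregs.

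The effect of the genotype in the tumour was asked by setting N, HetNrp1def and HetWT Tregs against WT, and the groups labelled deficient against each other and against HetWT. No gene passed the test in any of these 5 comparisons with edgeR, while 376, 341, 370, 291 and 213 genes had an unadjusted p under 0.05 (N, HetNrp1def and HetWT against WT, HetNrp1def against HetWT, and N against HetNrp1def). DESeq2 called 4, 10, 23, 12 and 11 genes. Nrp1 had log2 fold changes of -0.15 (SE 0.43) in N, -0.15 (SE 0.45) in HetNrp1def and -0.14 (SE 0.45) in HetWT tumour Tregs against WT. Ifng had 1.42 (SE 1.19), 0.90 (SE 1.24) and 0.65 (SE 1.24), and Foxp3 -0.15, 0.46 and 0.48. Between HetNrp1def and HetWT, Nrp1, Foxp3 and Ifng had -0.01, -0.02 and 0.25, and between N and HetNrp1def 0.00, -0.61 and 0.52. Without HetWT tumour replicate 2 (491 CPM of Ifng) Ifng in HetWT against WT was -0.68, and that in HetNrp1def against HetWT 1.72. Other leave-outs of 1 sample turned the sign of Nrp1 in all 5 comparisons, of Foxp3 in N and HetNrp1def against WT and HetNrp1def against HetWT, and of Ifng in the last 2 of the 5. Ifng in HetNrp1def against WT was 0.40 without HetNrp1def tumour replicate 3. Simulated 4-fold, 8-fold and 16-fold changes in N were recovered for 18%, 62% and 86% of 50 genes, which need not hold at low counts.

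Some gene lists moved as sets in the tumour, each with camera's preset correlation alone. Checkpoint receptors were higher than in WT in N (mean 0.80, adjusted p = 0.0120), HetNrp1def (0.75, 0.0498) and HetWT Tregs (0.88, 0.0184). With an estimated correlation the adjusted p were 0.204, 0.395 and 0.133, and the 3 comparisons share the WT samples. Without WT tumour ds1 the means were 0.46, 0.41 and 0.55 and none was called (adjusted p = 0.196, 0.233 and 0.184), and the call was lost in 1 of 10, 6 of 9 and 2 of 9 leave-outs. Melanoma markers were lower by means of -2.85, -1.42 and -1.48 (adjusted p = 0.326, 0.755 and 0.676 with an estimated correlation), and lower in N than in HetNrp1def Tregs (-1.43, adjusted p = 0.919 with an estimated correlation). In double-sorted libraries alone both N differences in melanoma markers were 2.63, higher and not lower. That rests on N tumour ds2 (mean 4.98 log2 CPM), without which the difference from WT was -0.10, and HetNrp1def has 1 double-sorted tumour sample. Leaving out 1 sample at a time, the melanoma difference ran from -2.76 to -0.51 (without HetNrp1def tumour replicate 2) in HetNrp1def, from -2.81 to -0.39 (without HetWT tumour ds2) in HetWT and from -2.49 to -0.16 (without HetNrp1def tumour replicate 4) in N against HetNrp1def, with 5 of 9 calls lost in each. Sterol genes were lower in N (-0.79) and HetWT (-0.73), with adjusted p of 0.374 and 0.622 with an estimated correlation. The HetWT value was -0.23 without HetWT tumour replicate 2, its call was lost in 5 of 9 leave-outs, and that of N was lost without N tumour ds1 (-0.60). Fibroblast genes were lower (-1.14) and endothelial genes higher (1.03) in N than in WT, and endothelial genes were higher in N than in HetNrp1def (1.14, but -0.17 in single-sorted libraries alone), with adjusted p of 0.523, 0.409 and 0.919 with an estimated correlation. The fibroblast value was -0.65 without WT tumour ds1 and -1.77 without WT tumour ds2. The endothelial values were 0.43 and 0.54 without N tumour ds2 and 1.62 and 1.73 without N tumour replicate 2, and the second was 1.71 without HetNrp1def tumour replicate 4. These 3 calls were lost in 4 of 10, 5 of 10 and 6 of 9 leave-outs. The naive list was higher in HetWT than in WT (0.27, adjusted p = 0.545 with an estimated correlation), and -0.47 with the authors' log2 values. Without WT tumour ds1 it was 0.16, its call was lost in 5 of 9 leave-outs, and the log2 value was 0.51 without WT tumour ds1 and ds2. No list was called for HetNrp1def against HetWT. Over all genes, no list member passed in these comparisons. Adjusted over the list alone, 1 naive gene, also in the conventional CD4 list, was lower in N than in WT and 1 semaphorin gene higher in HetNrp1def than in HetWT.

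HetNrp1def and HetWT tumour Tregs come from heterozygous mice, and both were set against the same WT samples to ask for a shift they share. Over 14668 genes the fold changes correlated with r = 0.560 (jackknife SE 0.223), across genes, which are not independent replicates. Unchanged groups simulated against the same controls gave 0.446 (0.427 to 0.462 in 50 simulations). The covariance was 0.467 against 0.494 simulated, a difference of -0.03. With the WT samples split between the comparisons in 10 ways, the mean r was -0.02 (-0.15 to 0.06).

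In lymph node Tregs, the same genotypes were compared outside the tumour. No gene passed with edgeR for N, HetNrp1def or HetWT against WT or for HetNrp1def against HetWT, with 616, 900, 599 and 952 genes at an unadjusted p under 0.05, and DESeq2 called 27, 217, 29 and 254. Nrp1 had log2 fold changes of -0.77 (SE 0.43), -0.87 (SE 0.46), 0.70 (SE 0.45) and -1.56 (SE 0.49) in that order, with adjusted p of 1, 0.845, 0.9997 and 0.497. Without HetWT lymph node ds1 (1439 CPM of Nrp1) the last 2 values were -0.31 and -0.55, and the difference in mean log2 CPM between HetWT and WT was 0.30 in all samples (exact p = 0.794). Ifng had 2.17, 0.94, 4.14 and -3.20, and Foxp3 0.46, 0.45, 0.14 and 0.31. Without HetWT lymph node ds1 (222 CPM of Ifng) the last 2 Ifng values were 2.19 and -1.26, and the HetNrp1def value was -0.32 without HetNrp1def lymph node replicate 2. Leaving out 1 sample at a time turned the sign of Foxp3 in each of the 4, with values from -1.37 to 3.34, -2.42 to 3.33, -0.60 to 3.02 and -2.56 to 1.04.

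The list of activated tumour Tregs was lower in HetNrp1def than in HetWT lymph node Tregs, by a mean of -1.16, and was the single list of the genotype comparisons called with the preset (adjusted p = 6.5e-06) and the estimated correlation (adjusted p = 0.00417). Of its 20 tested members 19 lay below 0, none passed over all genes, and 2 passed adjusted over the list alone. In single-sorted libraries alone, 2 samples per group, the mean was -0.94 (adjusted p = 1.2e-06, and 0.0773 with an estimated correlation), in double-sorted ones, also 2 per group, -1.38 (0.0708 and 0.547), and with the authors' log2 values -0.84 (0.00164 and 0.933). Proliferation genes were lower too (-0.96, adjusted p = 0.104 with an estimated correlation), and suppressive genes stood at -0.96 (adjusted p = 0.0633). The proliferation mean was -0.55 without HetNrp1def lymph node ds1, still called. HetNrp1def Tregs had lower activated (-0.46) and proliferation (-0.72) genes and higher NK cell genes (1.74) than WT, with adjusted p of 0.398, 0.398 and 0.984 with an estimated correlation. All 3 values shrank without HetNrp1def lymph node ds1, to -0.19, -0.31 and 1.09, and the NK cell value was 2.77 without ds2. Their calls were lost in 7, 0 and 5 of 9 leave-outs. With the replicate number as a block that activated mean was -0.42 (adjusted p = 0.0524 with the preset correlation). HetWT Tregs had higher identity (0.74), suppressive (0.91) and activated (0.70) genes than WT, with adjusted p of 0.241, 0.198 and 0.241 with an estimated correlation. These calls were lost in 7, 5 and 8 of 9 leave-outs. Adjusted over the list alone, 2 NK cell, 2 IFNg response and 2 sterol genes were higher in HetNrp1def than in WT, and 2 conventional CD4 genes higher in HetNrp1def than in HetWT. Type I interferon genes were lower in N than in WT (-0.96, 2 adjusted over the list alone, adjusted p = 0.553 with an estimated correlation).

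Whether the tissue change itself differed by genotype was tested as an interaction. With edgeR no gene passed for N, HetNrp1def or HetWT against WT, while 455, 614 and 568 had an unadjusted p under 0.05 and DESeq2 called 18, 23 and 25. Nrp1 had interaction terms of 0.62, 0.72 and -0.84, Ifng of -0.75, -0.04 and -3.50, and Foxp3 of -0.61, 0.02 and 0.34. Without HetWT lymph node ds1 the HetWT terms were 0.19 for Nrp1 and -1.51 for Ifng. Over all left-out samples Ifng ran from -1.19 to -0.43 in N and -0.66 to 1.36 in HetNrp1def, and Foxp3 from -3.49 to 1.22, -2.86 to 2.96 and -2.53 to 1.20 in the 3 genotypes. In N the tissue change was larger for type I interferon genes (0.71) and smaller for sterol (-0.80) and melanoma genes (-2.97), and in HetNrp1def larger for activated Treg (0.61) and proliferation genes (0.72). These calls were lost with an estimated correlation (adjusted p = 0.744, 0.744, 0.744, 0.407 and 0.746), and none was made for HetWT. With the preset, the calls other than melanoma were lost in 9 and 14 of 20 and 12 and 7 of 18 leave-outs. The melanoma term was 2.24 in double-sorted libraries alone, which hold N tumour ds2.

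The tissue change within N, HetNrp1def and HetWT Tregs was added as 3 comparisons after seeing the data. In each, tumour Tregs held less of the naive programme and more of the activated and glycolytic ones. Naive genes had means of -2.85, -2.59 and -2.30 (9, 11 and 5 of 18 called, 15, 16 and 11 adjusted over the list alone). Glycolysis genes had 1.83, 2.14 and 1.92 (5, 6 and 4 of 26 called, 15, 14 and 14 adjusted over the list alone). Suppressive genes had 2.73, 2.75 and 1.81, activated genes 1.65, 2.43 and 1.25, and type I interferon genes 2.41, 1.98 and 1.84. These lists, and the IFNg and Th1, IFNg response, checkpoint, chemokine, immediate early, CD8, B cell and conventional CD4 lists, were called in all 3 with the preset and the estimated correlation. Melanoma (adjusted p = 0.490, 0.244 and 0.136) and macrophage calls (0.0992, 0.218 and 0.0590) were lost with an estimated correlation, and the melanoma mean in HetWT was -0.44 in double-sorted libraries alone. The melanoma means of 1.81, 3.28 and 3.25 were 0.75 without N tumour ds2, where the call was lost, 2.01 without HetNrp1def tumour replicate 4 and 1.94 without HetWT tumour replicate 4. The macrophage mean of 1.62 in HetNrp1def was 0.99 without lymph node ds2, where the call was lost, and 2.68 without tumour ds2. With an estimated correlation the immediate early call was lost in 6 of 10 leave-outs in N and 1 of 8 in HetNrp1def (lymph node ds2), that of B cells in 1 of 10 in N (lymph node replicate 3), that of IFNg response in 4 of 8 in HetNrp1def and that of conventional CD4 genes in 1 of 8 in HetWT (lymph node pair 3 and 4). With edgeR 83 genes were higher and 33 lower in N, 51 and 45 in HetNrp1def, and 24 and 11 in HetWT. Without N lymph node replicate 2, HetNrp1def lymph node ds1 or HetWT tumour replicate 4, the totals of 116, 96 and 35 were 55, 42 and 18, the lowest of any left-out sample. They were 313, 190 and 93 with a replicate block, 150, 277 and 142 with 45 libraries as deposited, 3, 0 and 1 in double-sorted libraries alone, and 407, 777 and 281 with DESeq2. Library weights with the block gave the highest totals, 994, 976 and 700, and the authors' log2 values gave 346, 6 and 17. In HetNrp1def the balance turned with DESeq2 size factors in edgeR (55 higher and 123 lower), DESeq2 (222 and 555) and the replicate block (94 and 96). In HetWT it was 16 and 12 with DESeq2 size factors and turned with DESeq2 (108 and 173) and the log2 values (7 and 10), the latter turning it in N too (171 and 175).

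Nrp1 had log2 fold changes between tumour and lymph node of -0.45 in N, -0.35 in HetNrp1def and -1.91 in HetWT, Foxp3 of 0.03, 0.66 and 0.98, and Ifng of 4.04, 4.74 and 1.28, with adjusted p for Nrp1 of 0.862, 0.868 and 0.0850 and for Ifng of 0.187, 0.176 and 0.831. Without lymph node ds1 the HetWT values were -0.89 for Nrp1 and 3.26 for Ifng, and Ifng was 0.29, 2.04 and 2.00 without HetWT tumour replicates 2, ds2 and 4. Over all left-out samples Nrp1 ran from -0.56 to -0.22 in N and from -0.58 to 0.0670 in HetNrp1def, and Foxp3 from -0.29 to 1.86, 0.00638 to 3.52 and 0.54 to 1.75 in the 3 genotypes. Of 19 alternatives, 7 called Nrp1 in HetWT, and 3 and 6 called Ifng in N and HetNrp1def. Il10, the immunosuppressive cytokine, rose in N (5.22) and HetNrp1def (5.71), as did Prdm1, the transcription factor Blimp-1 of effector Tregs (3.59 and 3.87). Gzmb rose in N (5.77) and HetWT (6.39), as did Tbx21, the Th1 transcription factor T-bet (4.52 and 4.88). Leaving out 1 sample at a time, Il10 and Prdm1 in HetNrp1def and Tbx21 in HetWT each lost the call in 8 of 8 cases and Gzmb in HetWT in 5 of 8. In N, Il10 lost it in 4 of 10 cases, Klra3 in 6, and Prdm1 and Tbx21 in 1 each, without lymph node replicate 2. In N, Klra3 was at least 743-fold higher, and Gp49a had a ratio of 1859.8 (95% exact interval 636 to 9021). The lowest in N included Id3, an inhibitor of E proteins (-4.58), and Igfbp4 (-7.41). The 4 tissue comparisons share a fit but no samples. In all 4, 17 genes were higher and 8 lower, of 209 called in any, with 0 in opposite directions. WT and N shared 40 higher and 21 lower genes, and the part due to the shared fit was not tested. The 17, listed here whatever rule chose named genes, were Aldoa, AW112010, Bhlhe40, Gapdh, Gimap7, Glrx, Gp49a, Hif1a, Id2, Ifngr1, Iigp1, Litaf, Ly6a, Nkg7, Sla, Tnfrsf9 and Tpi1, and the 8 were Bcl2, Ccr7, Foxp1, Id3, Ift80, Igfbp4, Il6ra and Tcf7, chosen after their values were seen.

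**Figure D3:**
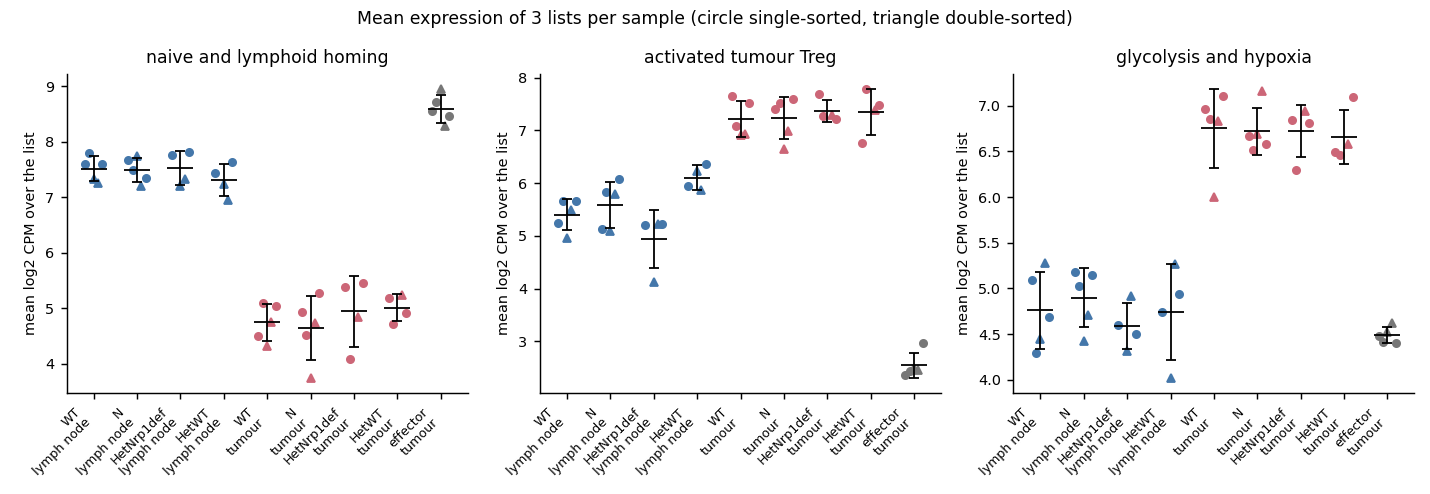
Mean log2 CPM of the naive, activated tumour Treg and glycolysis lists in each sample, by group. In the 4 genotypes the naive mean is lower and the glycolysis mean higher in tumour than in lymph node Tregs, with mean differences in WT of -2.77 and 2.00.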

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

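The tests of the authors' log2 values, of melanoma reads and of conventional T cells or genotype behind the activated Treg list were chosen after the results were seen, as were the counts of other sample splits for the WT tissue comparison and the first 4 genotype comparisons in the tumour, and the tissue comparisons of the other genotypes. The splits by same-numbered pairs, the leave-outs of samples for gene lists and the leave-out of N tumour ds2 were also added after the results were seen.

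Within groups, 73 sets of values were examined for a sample far from the rest, by the gap between the highest or lowest sample and its neighbour as a share of the group's range. Of these 14 passed the limit for their size, 9 at the highest and 5 at the lowest sample, where chance flags about 1 in 20 groups (3.65 of 73). Nrp1 stood apart in HetNrp1def lymph node ds1, with a gap of 0.939 of the range, and Ifng in N tumour ds2 (0.769). Faim3 stood apart in WT tumour replicate 2 (1) and Ms4a1 in WT tumour ds1 (0.846). Ccl3, Eps8 and Spp1 had 4, 3 and 3 counts in WT lymph node replicate 3 alone of that group (gap 1), where Gpr83 also stood apart (0.798). Among effector T cells, Ccl4 stood apart in replicate 4 and Gp49a and Il1r2 in ds1 (each 1), Lypd6b in ds1 (0.889), Pdlim4 in replicate 4 (0.816) and Dapl1 in ds2 (0.736).

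In tests of whether the tissue change differed from that of WT, 5 of 84 lists passed with camera's preset correlation. In N these were type I interferon (0.71), sterol (-0.80) and melanoma genes (-2.97), and in HetNrp1def activated Treg (0.61) and proliferation genes (0.72), as mean log2 differences. All 5 calls were lost with an estimated correlation. Without 1 sample they came to 0.42 (WT tumour ds1), 0.45 (N lymph node ds1) and 0.46 (WT lymph node ds2) for interferon, -0.51 (WT lymph node ds1) for sterol, and 0.34 and 0.31 (HetNrp1def lymph node ds1) for activated and proliferation genes.

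Other splits of the samples were counted for each comparison, the real one included, up to 100. For genes called, 1 of 100 splits gave as many in WT tumour against lymph node Tregs (real 128, highest other 3), in WT Tregs against effector T cells (838, 90) and in N tumour against lymph node Tregs (116, 0). The same tissue comparison gave 1 of 35 in HetNrp1def (96, 1) and HetWT (35, 1). These margins argue against chance. With 0 genes called, every split gives as many, which decides nothing. In the tumour the highest other split gave 1, 1 and 0 in N, HetNrp1def and HetWT against WT and 0 in N against HetNrp1def. It gave 1, 2 and 2 against WT in the lymph node and 4, 0 and 1 in the interactions. For HetNrp1def against HetWT it gave 0 in each tissue.

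With camera's preset correlation, 1 of 100 splits gave as many lists in WT tumour against lymph node Tregs (real 18, highest other 17). It was 1 of 35 in HetWT (17, 16), and neither margin excludes chance. Nor was it excluded in HetNrp1def (2 of 35, 17, 17), N (10 of 100, 16, 19) or against effector T cells (8 of 100, 20, 22). With an estimated correlation 1 of 100 splits gave as many in WT (14, 7), N (14, 13) and against effector T cells (16, 14). It was 1 of 35 in HetNrp1def (14, 4) and HetWT (13, 6). Wide margins argue against chance in WT, HetNrp1def and HetWT. In the tumour 10 of 100 splits gave as many in N (5, 8), 54 in HetNrp1def (2, 9) and 27 in HetWT (4, 8) against WT, and 83 in N against HetNrp1def (2, 11). In the lymph node 72 of 100 gave as many in N (1, 8), 34 in HetNrp1def (3, 9) and 27 in HetWT (3, 9) against WT, and 11 of 35 in HetNrp1def against HetWT (2, 7). For the interactions 42 of 100 gave as many in N (3, 8) and 43 in HetNrp1def (2, 9). Some of these genotype splits called several times the real number, but at most 2 lists with an estimated correlation. Why was not tested. Chance was not excluded for any of these counts of lists between genotypes. In the lymph node, splits that part the 4 same-numbered pairs, as the real one does, gave as many in 1 of 11 for HetNrp1def and 1 of 14 for HetWT against WT and 2 of 8 for HetNrp1def against HetWT (highest other 2, 1 and 3), too few for a share under 0.05.

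The first pattern is how few genes the authors' log2 values called for the WT tissue change, 7 against 128 from the counts. The tool and the smaller set of genes are argued against, since limma on log2 CPM of the same genes called 259, and so is removal of the replicate number, since adding it as a block gave 569. In the log2 values WT tumour ds2 had the lowest r with its own counts (0.289), that of ds1 (0.777) lay above those of 4 libraries, and naive genes had the opposite sign to the counts in 7 of 45 libraries, among them WT tumour ds1 (0.56 against -1.98) and ds2 (1.82 against -1.51). The ds2 sample alone is argued against as the whole cause, since 23 genes were called without it, and so is an exchange of 2 columns, because its highest r with any count column was 0.473. WT tumour ds1 and ds2 together may be the larger part of the cause. Without them 196 genes were called (262 from log2 CPM of the same samples), against 0 to 12 without any of the other 9 pairs of WT tumour samples. The step that changed the log2 values of these and other libraries is not given in the sources used here, and no biological explanation was tested.

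The second pattern is the lower activated Treg list in HetNrp1def than in HetWT lymph node Tregs (means 4.94 ± 0.55 and 6.10 ± 0.23 log2 CPM, n = 4 each). A single library is argued against, since all 8 leave-outs kept an adjusted p under 0.05 with an estimated correlation (real 0.00417, highest 0.0352). As small a p was given by 1 of 35 splits (real 0.000149, lowest other 0.0155), but only 8 of them part the same-numbered pairs, and this list was picked from 392 list tests, so chance stays open. More conventional T cells in one sort stays open, with conventional CD4 and Treg identity differences of 0.25 and -0.64 (exact p = 0.686 and 0.0571). So does Nrp1 loss acting alike in all mice, with 0.18 in N against WT (exact p = 0.437). Genotype may be part of the cause (-0.94 single-sorted, -1.38 double-sorted), but counts do not check the labels. WT (5.40 ± 0.30) lay nearer HetNrp1def, so Nrp1 loss leaves HetWT above WT unexplained.

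The third pattern is the higher glycolysis list in tumour Tregs beside melanoma reads in some of the same libraries. Melanoma cells or RNA are argued against as the whole cause, since 8 of 8 tumour Treg samples with a melanoma mean inside the lymph node range had glycolysis means of at least 6.50, above the highest lymph node sample at 5.28. With the melanoma mean as a covariate the glycolysis difference was 1.86 (adjusted p = 1.9e-07 with an estimated correlation). The lower melanoma list in N than in WT Tregs was -2.85 in all samples and 2.63 in the double-sorted ones, but -0.10 in the latter without N tumour ds2, so carry-over that varies from sort to sort stays open. A response of Tregs to the tumour tissue stays open as a hypothesis, as do other cells that were not listed.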

How the results depend on the processing

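The settings named below as added were chosen after seeing the data, as were the tissue comparisons of N, HetNrp1def and HetWT Tregs. Counts of genes called are given where they moved by over 1.5 times, and the cause was not tested unless stated.

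With DESeq2 size factors in edgeR, the tissue change in HetNrp1def Tregs gave 178 genes (55 higher and 123 lower, against 51 and 45), and HetNrp1def against HetWT lymph node Tregs gave 1. That scaling moved the median of all genes by 0.12 in the WT tissue comparison, -0.12 in HetWT against WT in the tumour, 0.18 and 0.11 in HetNrp1def and HetWT against WT in the lymph node, 0.12 against effector T cells, -0.28 and -0.22 in the HetNrp1def and HetWT interactions, and 0.11, -0.12 and -0.11 in the tissue comparisons of N, HetNrp1def and HetWT. Without a filter on low counts HetNrp1def gave 59 in the tissue comparison, and 18 with its own groups alone, which leaves fewer samples. Sorting as a covariate gave 58 for HetWT. Single-sorted libraries alone gave 362, 181 and 110 in the WT, N and HetWT tissue comparisons, and 1 each for HetWT against WT in tumour and lymph node. Double-sorted libraries alone gave 2, 3, 0 and 1 in the WT, N, HetNrp1def and HetWT tissue comparisons, 51 against effector T cells and 1 for HetNrp1def against WT in the lymph node. There each heterozygous tumour group is 1 sample, assumed to vary like the other groups.

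Same-numbered samples deviated from their group means together only in part, with r of −0.15 to 0.46 over 90 pairs (median 0.146), 59 over 0.1 and 59 best with their own number. Those over 0.1 were 13 of 13 for ds1 and 21 of 21 for ds2, but 11 of 21, 4 of 14 and 10 of 21 for numbers 2, 3 and 4. Melanoma means of HetWT and HetNrp1def tumour samples were -0.44 and -0.58 for number 2 and 3.93 and 3.62 for 3. They were -1.15 and -0.38 for ds2 and 6.06 and 5.96 for 4. That hints, from the data alone, at shared tumours, but Y-linked reads of ds2 differed (0 and 13.2 CPM). The numbers were taken to pair samples only in the 3 lymph node comparisons where every pair was over 0.1, and there the block ended 1 of 8 list calls, that of activated genes in HetNrp1def against WT (-0.42, adjusted p = 0.0524), and gave 0 genes. With the replicate block the tissue comparisons gave 382, 313, 190 and 93 genes in WT, N, HetNrp1def and HetWT, and the comparison with effector T cells 1284. With Y-linked reads as well (added), the tissue counts were 395, 307, 200 and 90, that against effector T cells 1292, and HetNrp1def and HetWT against WT in the lymph node gave 1 each.

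DESeq2 called 486, 407, 777 and 281 genes in the 4 tissue comparisons and 1574 against effector T cells. In the tumour it called 4, 10 and 23 for N, HetNrp1def and HetWT against WT, 12 for HetNrp1def against HetWT and 11 for N against HetNrp1def. In the lymph node it called 27, 217 and 29 against WT and 254 for HetNrp1def against HetWT, and 18, 23 and 25 for the interactions.

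From the authors' log2 values limma called 7, 346, 6 and 17 genes in the 4 tissue comparisons, 58 against effector T cells and 17 for N against WT in the tumour. With a block (added) it was 3, 222, 2 and 2, and 40 against effector T cells. Without the WT tumour ds2 library (added) it was 23, 382 and 17 in WT, N and HetNrp1def, 165 against effector T cells, 1 for HetWT against WT in the lymph node and 0 for N against WT in the tumour. Without WT tumour ds1 and ds2 (added) it was 196 in WT, 226 against effector T cells, and 31 and 1 for N and HetNrp1def against WT in the tumour. On log2 CPM of the same genes (added) limma called 259, 195, 175 and 78, and with a block 569, 411, 297 and 158, with 1683 against effector T cells and 1 each for HetNrp1def and HetWT against WT in the lymph node.

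Voom with library weights and a block (added) called 1236, 994, 976 and 700 genes in the tissue comparisons and 2622 against effector T cells. It called 16 for N against WT in the tumour, 4, 6 and 7 for N, HetNrp1def and HetWT against WT and 10 for HetNrp1def against HetWT in the lymph node, and 2 for the HetWT interaction. Without the ds1 libraries (added) the tissue counts were 345, 208, 175 and 117, and 1376 against effector T cells. With the melanoma mean as a covariate (added) the WT tissue count was 60. The 45 libraries as deposited (added), which count the near-identical pairs as separate, gave 277 and 142 for HetNrp1def and HetWT, and with a block 424, 350, 493 and 268 in the tissue comparisons and 1424 against effector T cells. A minimum log2 fold change of 1 left 128 and 837 genes in the WT tissue comparison and against effector T cells.

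Leaving out each sample in turn, the WT tissue count ran from 78 (without WT tumour replicate 2) to 122, with 84 and 82 without WT lymph node replicate 2 or ds1, and that against effector T cells from 667 to 806. In N it ran from 55 (without N lymph node replicate 2) to 87. In HetNrp1def it ran from 42 (without lymph node ds1) to 76, with 59 and 57 without lymph node replicates 2 and 4, and 46, 51, 53 and 58 without tumour replicates 2, 3, ds2 and 4. In HetWT it ran from 18 (without tumour replicate 4) to 31, with 22 without lymph node ds2, and 22 and 19 without tumour replicates 2 and 3. The comparisons with 0 genes stayed at 0. Of the called genes the text may name, 22 of 41 in the WT tissue comparison and 70 of 81 against effector T cells kept their call in every leave-out, as did 24 of 44, 16 of 34 and 10 of 16 in the N, HetNrp1def and HetWT tissue comparisons. Among others, Car6, Ccl5, Ccr6, Cited1, Dapl1, Eps8, Fosl2, Ifi27l2a, Ifit3, Il12rb2, Isg20, Lag3, Mlana, Ms4a1, Pmaip1, Spp1 and Xcr1 lost it in the former at least once, and Dct, Fdps, Gadd45b, Gata3, Gbp7, Ly6c2, Pik3cd, Pik3ip1, Tyr and Zbtb46 in the latter.

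Gene list calls over the 14 planned comparisons were 65, with 31 with an estimated correlation, 39 with fry and 113 from the authors' log2 values. They were between 50 and 66 with the block, single-sorted or double-sorted libraries, no ds1 libraries, 45 libraries or the melanoma covariate. Leaving out 1 sample at a time (added for lists) moved the mean of a called list by over 1.5 times for 1 of 18 lists in the WT tissue comparison, 0 of 20 against effector T cells, and 2 of 16, 3 of 17 and 2 of 17 in the N, HetNrp1def and HetWT tissue comparisons. In the tumour it did so for 3 of 5, 2 of 2 and 4 of 4 lists in N, HetNrp1def and HetWT against WT and 2 of 2 in N against HetNrp1def. In the lymph node it was 0 of 1, 3 of 3 and 0 of 3 against WT and 1 of 2 in HetNrp1def against HetWT, and 2 of 3 and 2 of 2 in the N and HetNrp1def interactions. None of these means changed sign. The correlation of the shared shift was -0.0183 with split controls.

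A change of sign is counted for a gene where either setting passes the threshold, and for a list by its direction against the other genes. In double-sorted libraries Ms4a1 was 0.10 in the WT tissue comparison and Dct -0.45 against effector T cells. Against effector T cells the authors' log2 values gave 0.57 for Bcl2, -0.0862 for Zbtb46 and -0.36 for Fosl2, the same with a block, and 0.35 and -0.0135 for Bcl2 and Zbtb46 without the WT tumour ds2 library. The endothelial list was -0.17 for N against HetNrp1def in single-sorted libraries. In double-sorted libraries the B cell list was 0.59 in the WT tissue comparison, the macrophage list -0.88 in that of HetNrp1def, and the melanoma list 2.63 for N against WT and against HetNrp1def, -0.0888 against effector T cells, 2.24 for the N interaction, and 0.28 and -0.44 in the HetNrp1def and HetWT tissue comparisons. From the authors' log2 values the WT tissue comparison gave 0.14 for suppressive, 0.0672 for activated, -0.48 for checkpoint and -0.67 for proliferation genes. In those values naive genes, taken from the mean of the replicate number, had the opposite sign to the counts in 7 of 45 libraries. These were WT tumour ds1 (0.56 against -1.98) and ds2 (1.82 against -1.51), HetWT tumour replicate 2 (0.38 against -1.37), HetNrp1def tumour replicate 2 (0.0513 against -1.18), and the lymph node libraries N ds2 (-0.69 against 0.89), HetWT ds2 (-0.12 against 0.66) and WT ds1 (-0.0205 against 1.06). Without WT tumour ds2 those 4 means were 0.68, 0.62, -0.14 and -0.36, and without WT tumour ds1 and ds2 1.15, 0.97, 0.20 and -0.27 (added). The same values gave -0.47 for naive genes in HetWT against WT in the tumour, -0.16 for proliferation genes in the HetWT tissue comparison, and -0.0738, 0.0169 and -0.000286 for type I interferon, AKT and immediate early genes against effector T cells. Without both samples the naive value was 0.51 and the last 3 were 0.65, -0.15 and 0.43. Counting each called named gene once under each setting other than leave-outs, 3238 values kept direction and call, 844 lost the call and 10 changed sign. For called lists the numbers were 800, 205 and 18.

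The ds2 libraries were the shallowest, with 2945638 to 5408375 counts, and 4-fold changes were recovered for 20% of simulated genes in the WT tissue comparison. How depth bears on the calls was not tested.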

Other observations

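The comparisons of effector T cells with lymph node Tregs, and the choice of lists in them, were made after the values were seen.

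Libraries labelled effector T cells of tumours, a label not tested, carried more of the naive programme than lymph node Tregs. The naive list had a mean of 8.60 ± 0.25 log2 CPM in effector T cells and 7.52 ± 0.22 in WT lymph node Tregs (SD, n = 5). The difference was 1.08 over WT, 1.11 over N, 1.07 over HetNrp1def and 1.28 over HetWT lymph node Tregs. The activated Treg list was lower in effector T cells, by means of -2.86, -3.04, -2.40 and -3.56 in the same order, and the proliferation list by -3.54, -3.85, -2.83 and -3.79. The conventional CD4 list, which shares 7 genes with the naive one, was higher by 2.14, 1.56, 2.08 and 2.33. Each of these 16 differences had an exact two-sided permutation p of 0.00794, the smallest these group sizes allow, and the same adjusted p. The glycolysis mean was 4.49 ± 0.09 in effector T cells, 4.76 ± 0.42 in WT lymph node Tregs and 6.76 ± 0.43 in WT tumour Tregs.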
